A study of Cricetiscus sungorus with 16 samples.

How the data were processed

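Total RNA from both ovaries of each hamster was amplified, labelled with Cy3 and hybridised to a mouse array of 45018 spots, with 1 colour and 1 hamster per array, per the labels' protocols and the file headers. The labels give each sample its own animal code, so the 4 arrays of a group are taken as 4 separate hamsters. Per the file headers, the authors scanned 4 slides of 4 arrays on 3 days and extracted the spots with Agilent Feature Extraction 10.5.1.1, which corrects background and detrends within an array. The deposited scanner files give the processed intensity of each spot on a linear scale, not normalized between arrays. The authors' deposited value table holds the same intensity values rounded, linear and not centred, with column medians from 26.6 to 91.5. Except for 4 cells of a single column, it matched the scanner files to within 0.5%, and it was used as an alternative. Other columns used from the deposited files, per the file headers, are flags for outlier spots and for signal well above background.

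Samples were grouped by their descriptions. For the 4 SD samples at 8 wk the labels conflict: the title and treatment fields give 16 h of light beside the letters SD, and the description gives 10 h. They were taken as SD with 10 h of light, which could not be checked from another source. The labels give no replicate numbers, and those used here are the slide's number in each group.

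Intensities were taken as log2 of the processed signal minus each array's 75th percentile, with spots flagged as outliers left out and spots of a probe averaged. Control spots were removed, leaving 43379 spots of 41174 probes. A probe was kept if it was well above background on all 4 arrays of at least 1 group, which 24998 probes were (60.7%). It had to be measured on at least 12 of the 16 arrays and at least 2 of each group and slide. The brightest probe stood for each transcript identifier, which left 20143 identifiers. No spot was saturated. For called identifiers with other probes past the filter, 45 of 53 other probes had the same direction in the photoperiod comparison at 8 wk, 144 of 167 in the LD age change and 463 of 541 in the SD age change (84.9%, 86.2% and 85.6%). Over all identifiers the shares were 66.1%, 69.4% and 71.1%.

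Each comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend) over all 16 arrays, so that the groups shared 1 estimate of the spread, with Benjamini-Hochberg adjustment over the 20143 identifiers and a threshold of 0.05. The interaction is the SD age change minus the LD age change. The slide was not in the fit, as fixed before the data were examined, and the fit with slide as a fixed block was fixed beforehand as an alternative. Arrays of the same slide deviated from their group means together, with a median correlation of 0.450 and a lowest of 0.228. The fit was tested on simulated arrays for the 3-wk comparison, with 200 transcripts changed by known folds. Noise was drawn for each transcript on its own, with the residual spread of the fit with the block over all 16 arrays. Of transcripts made 1.5-, 2- and 4-fold different, the fit without the block called 1, 27 and 58, with 0 false calls among the rest. With the block it called 27, 56 and 62, with 8 false calls.

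Of the rule for named genes, only the part on size could be applied, without its condition on gene symbols. Eligible in a pairwise comparison were transcripts past the threshold whose measured arrays of 1 group did not overlap those of the other. Named were the 2 with the largest rise and the 2 with the largest fall. For the interaction the 2 largest positive and the largest negative were named, without the condition on overlap. In pairwise comparisons this condition fixes the same direction on every slide, so agreement of slides in sign adds no support. The files do not pair identifiers with gene symbols, so none of the genes, gene lists and cell type markers fixed before the data were examined could be matched, and no list was tested.

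Alternatives covered normalization, the filter, the use of probes, the trend, array weights, the slide block, the deposited value table, fitting only the 2 groups compared, a 2-fold minimum and leaving out each array. The background correction planned on mean signals was not run because the files give median signals. It was replaced, after the data were seen, by normexp with an offset of 50 on median signals. Also chosen after seeing the data were fits with outlier spots kept, without slide 1 and on pairs of slides. The number of arrays limits the precision of every value. The correlations across transcripts have a jackknife error over slides of 0.0748 for the age changes and 0.114 for the photoperiod differences.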

Results

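Gene expression was measured in the ovaries of female Siberian hamsters, a seasonal breeder in which day length sets the pace of reproductive maturation. The animals had been carried through gestation and reared in long days (LD, 16 h of light) or short days (SD, 10 h of light), and ovaries were taken at 3 or 8 wk of age. The 4 groups held 4 hamsters each, and RNA from both ovaries of a hamster was hybridised to a single-colour mouse oligonucleotide array, giving 16 arrays. The submitters' title and design ask how the ovary develops under each day length: whether SD and LD ovaries differed at 3 wk and at 8 wk, and how the ovary changed between these ages in each photoperiod.

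Hamster RNA gave signal on most of the mouse probes: between 58.0% and 75.7% of the 41174 probes were well above background on an array. The 75th percentile of intensity ran from 269 to 1007 and was lowest on slide 1. Of 33272 transcript identifiers on the array, 20143 passed the detection filter and were tested. The probes were made for mouse transcripts, and whether a probe's signal came from the matching hamster transcript was not tested. Changes given below are therefore changes of probe signal. The files give these identifiers without gene symbols, so transcripts are named here by identifier alone, no gene list or cell type marker could be matched, and at most 2 that rose and 2 that fell are named per comparison. Levels are log2 intensities relative to the 75th percentile of the array, given as mean ± SD, and each transcript is set only against itself in another group.

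The largest differences between arrays followed the slide rather than the animal's group. Each of the 4 slides carried 1 array of every group, and across 18648 transcripts measured on every array the slide held 43.7% of the variance, the group 32.0% and the remainder 24.3%. The first principal component took 35.5% of the variance and set slide 1 apart. With the slide effect removed it took 42.1% and ordered the groups by age, with mean scores of −29.6 ± 7.61 in LD and −27.5 ± 7.66 in SD at 3 wk, 15.6 ± 3.86 in LD at 8 wk and 41.5 ± 8.08 in SD at 8 wk (SD, n = 4). Counts of calls below are therefore given with those from the same fit with slide as a block. A group always held the same place on the slide, so place on the slide and group cannot be told apart in any comparison.

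**Figure D1:**
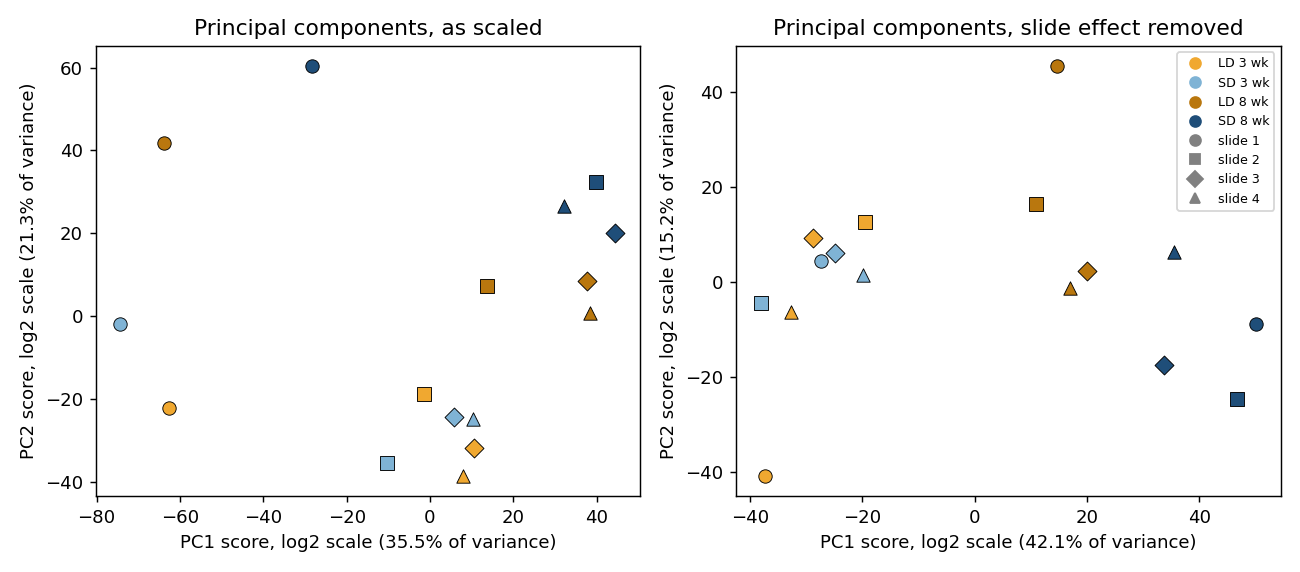
Scores of the 16 arrays on the first 2 principal components of log2 intensity, as scaled (left) and with the slide effect removed (right), coloured by group, with circles, squares, diamonds and triangles for slides 1, 2, 3 and 4. Slide 1 stands apart on the left. On the right the 3-wk groups lie together at means of −29.6 and −27.5, and the 8-wk groups lie at 15.6 in LD and 41.5 in SD.

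The comparison of SD with LD ovaries at 3 wk asked whether day length had altered expression by that age. No transcript passed the threshold in limma, either without the block or with slide as a block. At an unadjusted p under 0.05 there were 330 transcripts (1.64%) without the block and 1298 (6.44%) with it. The 95% interval of the difference lay within 2-fold for 84.9% of transcripts, and for 92.9% with slide as a block. Differences measured on separate slides had little in common, with correlations across transcripts between −0.181 and 0.214 for the 6 pairs of slides. Noise in simulated arrays took the residual spread of the fit with slide as a block over all groups, not of this comparison alone. Tested over 20143 transcripts, the fit without the block called 40.3% of 67 transcripts made 2-fold different and 87.9% of 66 made 4-fold different. With the block these shares were 83.6% and 93.9%. Of 67 transcripts made 1.5-fold different, 1.49% were called without the block and 40.3% with it. Most differences of that size were thus missed in both fits.

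At 8 wk, SD ovaries differed from LD ovaries in 193 transcripts, of which 148 were higher and 45 lower in SD, and 154 differed at least 2-fold (221 with slide as a block). NM_001033364 stood at −2.87 ± 0.25 in LD and −2.97 ± 0.29 in SD at 3 wk, at −3.02 ± 0.25 in LD at 8 wk and at 3.05 ± 0.95 in SD at 8 wk (SD, n = 4). It was 67.2-fold higher in SD (log2 6.07, SE 0.34, limma adjusted p = 1.17e-07), by 5.01 to 6.76 within slides. The condition on overlap used to pick the transcripts named here fixes their sign on every slide, so only the sizes within slides are informative. NM_013547 was 59.8-fold higher in SD (log2 5.90, SE 0.46, limma adjusted p = 1.39e-05), and higher on each of the 3 slides on which both arrays measured it, by 5.21 to 6.85. NM_153539 was lower in SD (log2 −4.65, SE 0.91, limma adjusted p = 0.0183), with differences from −6.80 to −0.77 within slides. It was well above background on only 1 of the 4 SD arrays, so the size of −4.65 rests on signals near background. With signals under the lowest one well above background raised to it on each array, the difference was −3.36. NM_183191 was well above background on none of the 4 SD arrays and on all 4 LD arrays, and was at least 4.60-fold lower in SD (limma adjusted p = 0.0234). Its differences within slides ran from −6.81 to −0.77 (log2), with SD signals not well above background. The bound sets the LD mean against, on each SD array, the higher of the lowest signal well above background and the probe's own. It was 2.90-fold without LD 8-wk replicate 1 and 7.26-fold without LD 8-wk replicate 3. With normexp, a background correction, the differences were 5.09 for NM_001033364 and 5.48 for NM_013547, and both falls lost their call, at −1.87 (SE 0.48, limma adjusted p = 0.102) for NM_153539 and −1.15 (SE 0.47, limma adjusted p = 0.619) for NM_183191.

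With slide as a block, 528 transcripts differed between SD and LD at 8 wk, 366 higher and 162 lower in SD, and all 193 were among them. Slide pairs shared this difference with correlations across transcripts between 0.056 and 0.496. The count fell to 118 without LD 8-wk replicate 2, 119 without SD 8-wk replicate 2 and 121 without SD 8-wk replicate 3, and to 82 when only these 8 arrays were fitted. Without slide 1 neither of the named falls passed in limma: NM_153539 differed by −4.50 (SE 1.05) at an adjusted p of 0.0754 (0.00047 to 0.407 over 33 alternative settings), and NM_183191 was at least 3.31-fold lower at one of 0.132 (0.00083 to 0.619). On slides 3 and 4 alone, with slide as a block, neither passed (limma adjusted p 0.407 and 0.300). In LD at 8 wk NM_183191 stood at −1.01 and −1.66 on slides 1 and 2 and at −4.99 and −4.39 on slides 3 and 4. The bound for NM_183191 thus rests mainly on slides 1 and 2. Without SD 8-wk replicate 4, the single SD array well above background for NM_153539, this transcript was at least 16.1-fold lower in SD. That array stood at −2.76, against −1.99 in LD on the same slide, so the 16.1-fold bound does not hold for all 4 SD arrays. Leaving out single arrays, NM_153539 lost its call without LD 8-wk replicate 2 or SD 8-wk replicate 1, 2 or 3 (limma adjusted p 0.0617 to 0.0854), and NM_183191 without LD 8-wk replicate 1 or 2 or SD 8-wk replicate 1 or 2 (0.0610 to 0.101).

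Between 3 and 8 wk in long days, 601 transcripts changed, 243 rising and 358 falling, and 348 changed at least 2-fold (562 with slide as a block). NM_145594 rose 11.3-fold (log2 3.50, SE 0.55, limma adjusted p = 0.0043), from −4.39 ± 0.30 to −0.89 ± 0.61 (SD, n = 4), with 3 of the 4 arrays at 3 wk well above background. AK009938 rose 10.2-fold (log2 3.35, SE 0.77, limma adjusted p = 0.0251), by 1.15 to 4.75 within slides. AF009414 fell 6.16-fold (log2 −2.62, SE 0.62, limma adjusted p = 0.0312), from 2.24 ± 0.72 to −0.39 ± 1.14 (SD, n = 4). NM_021459 fell 5.23-fold (log2 −2.39, SE 0.48, limma adjusted p = 0.0133). All 4 moved the same way on 4 of 4 slides, as the condition on overlap used to pick them requires. Both transcripts that rose in LD also rose in SD, NM_145594 by 5.31 (SE 0.55, limma adjusted p = 3.46e-05) and AK009938 by 3.71 (SE 0.77, limma adjusted p = 0.0060) on the log2 scale. Both that fell in LD also fell in SD, with changes of −2.78 for AF009414 (SE 0.67, limma adjusted p = 0.0161) and −2.70 for NM_021459 (SE 0.48, limma adjusted p = 0.0022). NM_145594 was well above background on 3 of the 4 SD arrays at 3 wk, and with the signal of the other raised to the lowest one well above background its SD change was 5.01. With normexp the LD changes were 2.06 for NM_145594, 2.52 for AK009938 and −1.70 for NM_021459 (log2).

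With slide as a block, 2394 transcripts changed with age in LD, 791 rising and 1603 falling, and all 601 were among them. The count depended on single arrays: it was 232 without LD 3-wk replicate 4, 350 without LD 8-wk replicate 2, 322 without LD 8-wk replicate 3 and 315 without LD 8-wk replicate 4. In the same fits AF009414 lost its call without LD 3-wk replicate 1, 3 or 4 or LD 8-wk replicate 2, 3 or 4 (limma adjusted p 0.0637 to 0.103). AK009938 lost it without LD 3-wk replicate 1 or 4 or LD 8-wk replicate 2 or 4 (0.0792 to 0.0869), and also without slide 1 (limma adjusted p = 0.0812, and 0.0099 to 0.172 over its alternative settings). NM_021459 lost it without LD 3-wk replicate 4 (limma adjusted p = 0.0565, and 0.0059 to 0.258 over its alternative settings). Slide pairs shared the LD age change with correlations across transcripts between 0.206 and 0.524.

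Between 3 and 8 wk in short days, 1844 transcripts changed, 961 rising and 883 falling, and 955 changed at least 2-fold (1175 with slide as a block). NM_013547 rose 145.6-fold (log2 7.19, SE 0.46, limma adjusted p = 6.70e-07), from −3.03 ± 1.06 (SD, n = 4) to 4.16 ± 0.23 (SD, n = 3). NM_001081372 rose 71.7-fold (log2 6.16, SE 0.38, limma adjusted p = 1.47e-07), from −0.38 ± 0.67 to 5.78 ± 0.55 (SD, n = 4), and by 4.94 to 6.97 within slides. AK004158 fell 10.4-fold (log2 −3.38, SE 0.75, limma adjusted p = 0.0095), from 3.15 ± 0.65 to −0.23 ± 1.47 (SD, n = 4). Its other probe gave −3.37. NM_008381 fell 9.64-fold (log2 −3.27, SE 0.52, limma adjusted p = 0.00085), from 6.12 ± 0.57 to 2.85 ± 1.5 (SD, n = 4). Its other probe gave a fall of less size, −0.75, so the size of this change differs between probes. In LD NM_001081372 also rose, by 3.12 (SE 0.38, limma adjusted p = 0.00091), and its interaction was 3.04 (limma adjusted p = 0.0501). AK004158 changed by −2.64 in LD (SE 0.75, limma adjusted p = 0.0744, or 0.0030 with slide as a block). NM_008381 changed by −0.81 in LD (SE 0.52, limma adjusted p = 0.593), and its interaction was −2.46 (limma adjusted p = 0.688).

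With slide as a block, 4655 transcripts changed with age in SD, 2202 rising and 2453 falling, and all 1844 were among them. Slide pairs shared the SD age change with correlations across transcripts between 0.582 and 0.724. The count was 1141 without SD 3-wk replicate 2 and 1183 without SD 8-wk replicate 2. Without SD 8-wk replicate 4 the change was −3.99 for NM_008381 and −2.78 for AK004158, on slides 3 and 4 alone, with the block, it stood at −1.93 for NM_008381 and did not pass (limma adjusted p = 0.117, and 2.76e-06 to 0.117 over its alternative settings), and with normexp NM_013547 changed by 6.17 (log2).

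**Figure D2:**
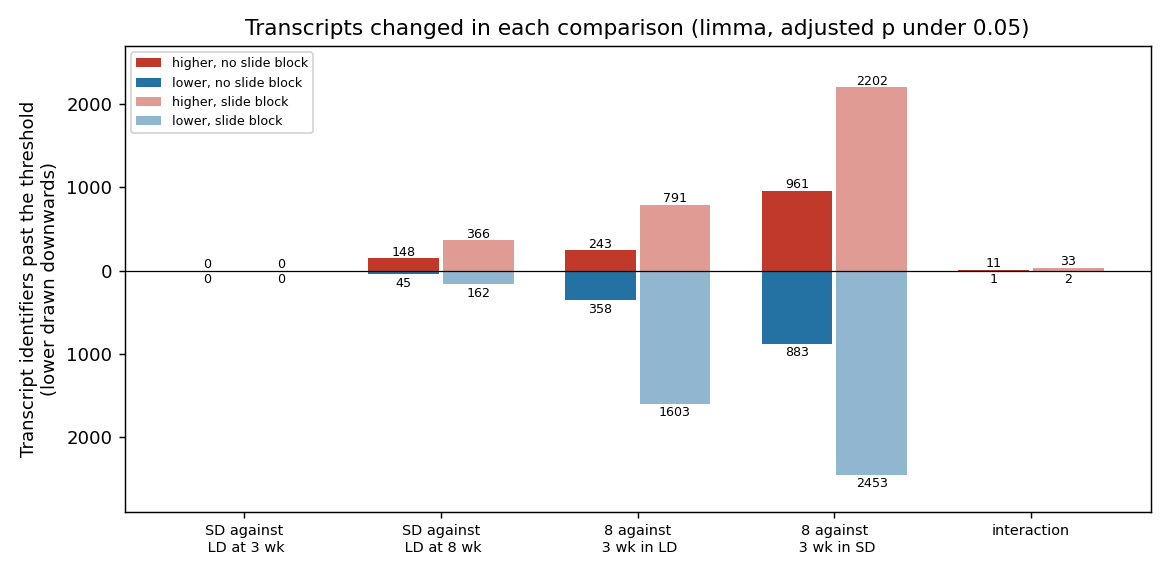
Number of transcript identifiers past a limma adjusted p of 0.05 in each comparison, higher drawn upwards and lower downwards, in solid bars without the slide block and in pale bars with it. The 3-wk photoperiod comparison has 0, the SD age change has 1844 without the block and 4655 with it.

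Age changes in the 2 photoperiods resembled each other. No array is shared between these comparisons. Across the 20143 transcripts, which are not independent replicates, the age change in SD correlated with that in LD at r = 0.675 (Spearman 0.613), and with slide as a block at r = 0.681. Within slides 1, 2, 3 and 4 it was 0.285, 0.465, 0.480 and 0.504. Of the 601 transcripts changed in LD, 506 also changed in SD, 186 rising and 320 falling in both and 0 moving in opposite directions. Independent lists of these sizes would share 11.6 rising and 15.7 falling. Both lists use 1 estimate of each transcript's spread from all 16 arrays, which favours the same transcripts in both, so they are not independent. The block fit gave 1867 changed in both, 602 rising, 1261 falling and 4 in opposite directions. The 1844 and 601 calls are not themselves a test that the age changes differ. On slides 3 and 4 alone, with slide as a block, 1075 transcripts changed in SD and 1321 in LD, so the larger SD count did not hold within those slides. On slides 1 and 2 alone they were 1351 and 0. At an unadjusted limma p under 0.05 there were 4470 and 2563 on those slides, so the 0 does not show an absence of change in LD.

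The photoperiod differences at 3 and 8 wk correlated at r = 0.175 across transcripts (Spearman 0.093), with no array shared, and at 0.181 with slide as a block. Within slides 1 to 4 it was −0.105, 0.129, 0.151 and 0.221. Single arrays moved it: it was 0.321 without LD 8-wk replicate 1 and 0.264 without SD 3-wk replicate 1, and 0.106, 0.105, 0.075, 0.094 and 0.064 without LD 3-wk replicate 1, LD 8-wk replicate 3, LD 8-wk replicate 4, SD 3-wk replicate 3 and SD 8-wk replicate 1. Without the filter on dim probes it was 0.012, and −0.045 on slides 1 and 2 alone. Of the 193 transcripts that differed at 8 wk, 152 (78.8%) had a difference of the same sign at 3 wk, where none passed the threshold, against 52.4% of all transcripts. The block fit gave 385 of 528.

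The test of whether the age change differed between photoperiods gave 12 transcripts, 11 with a more positive change in SD and 1 with a more negative change, or 35 with slide as a block, 33 and 2. Correlations of this difference across transcripts lay between −0.032 and 0.256 for the 6 pairs of slides. NM_001033364 changed by −0.15 (SE 0.34, limma adjusted p = 0.961) in LD and by 6.02 (SE 0.34, limma adjusted p = 6.67e-08) in SD on the log2 scale, a difference of 6.17 (SE 0.48, limma adjusted p = 1.65e-05). NM_013547 rose in both photoperiods, by 2.23 in LD (SE 0.43, limma adjusted p = 0.0122) and by 7.19 in SD, a difference of 4.95 (SE 0.63, limma adjusted p = 0.0058). ENSMUST00000088612 had the more negative change, a difference of −1.44 (SE 0.24, limma adjusted p = 0.0364). It stood at 0.37 ± 0.30 in LD and 0.35 ± 0.20 in SD at 3 wk, and at 1.38 ± 0.25 in LD and −0.08 ± 0.10 in SD at 8 wk (SD, n = 4). ENSMUST00000088612 lost its call in 12 of the 16 fits that left out a single array, keeping it only without LD 3-wk replicate 1 or 2, LD 8-wk replicate 3 or SD 8-wk replicate 4 (limma adjusted p 0.0552 to 0.119 in the 12). The difference for NM_013547 did not pass without slide 1 (4.66, limma adjusted p = 0.0999, and 6.9e-05 to 0.604 over its alternative settings). The number of transcripts was 4 without slide 1, 49 without SD 8-wk replicate 4 and 30 without LD 8-wk replicate 3. It was 6 or 7 without LD 3-wk replicate 3 or 4, LD 8-wk replicate 2 or 4, SD 3-wk replicate 1, 2 or 4, or SD 8-wk replicate 2 or 3. Of 100 assignments of the photoperiod labels within each age, the real one included, 8 gave at least 12 transcripts, among them the 4 draws that parted the 8-wk arrays as the real labels do and so hold the 8-wk difference. In the fit with the block, 4 of the 100 gave at least 35. With labels drawn only between the arrays of a slide, 13 of 100 gave as many in either fit, the real labels and 12 draws that kept the 8-wk parting, and the other draws gave 0. On slides 3 and 4 alone, with the block, none of these 3 differences passed in limma, at 5.78 for NM_001033364, 3.93 for NM_013547 and −1.43 for ENSMUST00000088612. For NM_001033364 normexp gave 5.18, and for NM_013547 array weights gave 4.35 (log2).

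**Figure D3:**
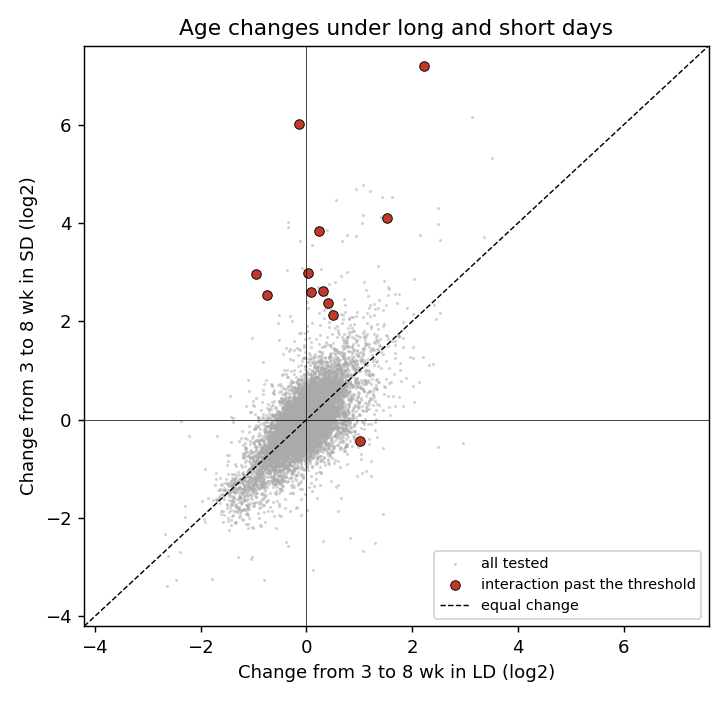
Change from 3 to 8 wk in SD (log2, vertical) against that in LD (log2, horizontal) for the 20143 transcripts tested, with the 12 past the threshold for a difference between photoperiods in red and a dashed line where both changes are equal. The cloud rises along the line (r = 0.675), and 11 of the 12 red points lie above it.

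**Figure D4:**
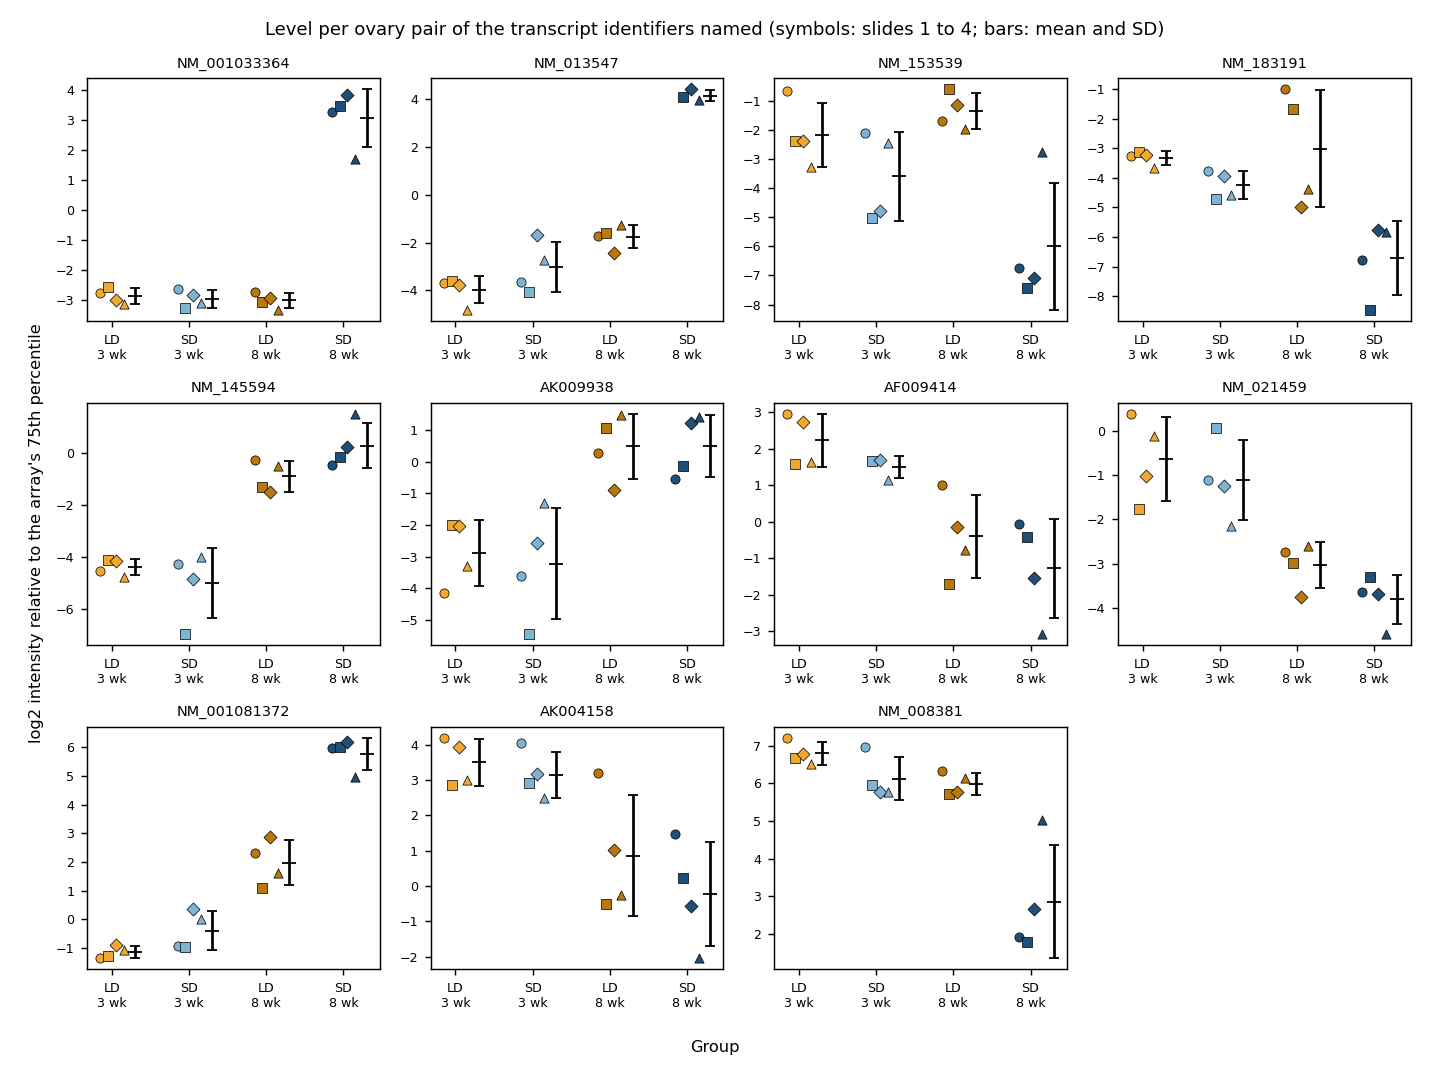
Level of the named transcripts, other than ENSMUST00000088612, in each hamster, as log2 intensity relative to the array's 75th percentile, by group, with circles, squares, diamonds and triangles for slides 1, 2, 3 and 4 and bars for the mean and SD. NM_001033364 stands at a mean of 3.05 in SD at 8 wk and at −3.02 in LD at 8 wk.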

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

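All tests of explanations below were chosen after the results they bear on had been seen.

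Whether chance assignment of hamsters to groups could give as many calls was tested by refitting every split of the 8 arrays of each pairwise comparison into groups of 4. For SD against LD at 8 wk, 1 of 35 splits gave as many, the real one with 193, and the highest other gave 39. For the age change in LD, 1 of 35 gave as many, the real one with 601 against 1. For the age change in SD, 1 of 35 gave as many, with 1844 against 2. Over splits that take no account of the slide, the real one thus gave the most calls in these 3 comparisons. Arrays of a slide resemble each other and each slide holds 1 array of every group, so these splits do not exclude chance. Of these splits, 8 part the 2 arrays of every slide as the real one does. Among them the highest other gave 0 at 8 wk, 1 for the LD and 0 for the SD age change, and 8 are too few for a share under 0.05. At 3 wk the real count was 0, all 35 splits gave at least that, and the highest gave 4. For the interaction, 8 of 100 draws of the photoperiod labels within each age, the real one included, gave at least 12, and the highest gave 360, which points to a structure of the samples. Besides the real labels, 4 of these 8 draws parted the 8-wk arrays as the real labels do, and 3 did not. With slide as a block, 4 of 100 draws gave at least the real 35 and the highest gave 297. With labels drawn only between arrays of a slide, 13 of 100 gave as many in either fit: the real labels and the 12 draws that parted the 8-wk arrays as the real labels do, with the highest other draw at 0. High counts without the 8-wk parting thus came from draws across slides, and the block did not remove them, since such draws still reached 124 with it. Draws that keep the 8-wk parting hold the 8-wk difference itself, so these draws do not decide whether chance gives the interaction count.

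More transcripts changed with age in SD (1844) than in LD (601). Dim arrays of slide 1 do not account for it, since without that slide the SD count was still 2.30 times the LD count, against 3.07 times with all slides. Arrays of slides 1 and 2 may account for it: on slides 3 and 4 alone, with slide as a block, the SD count was 0.814 times the LD count, against 1.94 times with 4 slides and the block. The place of the array on the slide stays open, since each group held 1 place on every slide. A larger change of the ovary in short days stays open as well. The spread over transcripts (standard deviation) of the age change in short days was 0.893, 1.78, 1.04 and 0.967 times that in long days on slides 1 to 4, above it by over 1.5 times on slide 2 alone. Over all slides it was 1.33 times, with 1266 transcripts over 2-fold in short days and 696 in long days, called or not, and the interaction test gave 12 transcripts.

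The spike-in controls, synthetic RNAs meant to be added at labelling and used here in no comparison, were bright on slides 1 and 2 and dark on slides 3 and 4. The brightest of 10 such controls had a median intensity of at least 124702 on each of the 8 arrays of slides 1 and 2, and at most 38.3 on slides 3 and 4. Weak hybridisation or scanning of slides 3 and 4 as the whole cause is argued against by their 75th percentile of ovary signal, whose lowest value, 819, was not below the highest on slides 1 and 2, 810. The bright corner controls were dimmer on slides 3 and 4, at 63185 to 86113 against 108600 to 145719, by at most 2.31 times, where the spike-in differed by at least 3259 times. Weaker scanning as a part of the difference stays open. A candidate explanation is that spike-in RNA was left out of the labelling of slides 3 and 4, which would give values at this low level. No biological explanation was tested.

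At 3 wk fewer transcripts had an unadjusted p under 0.05 than chance gives, 1.64% without the slide block. Slide differences counted as noise may account for this: with slide as a block the share was 6.44%, and in simulated unchanged transcripts it was 0.837% without the block and 4.90% with it.

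Of 58 sets of 4 arrays of a group, 7 held an array far from the other 3, where chance flags about 1 in 20. Outlier spots numbered 1278, 775, 1091 and 870 on the slide 1 arrays of LD at 3 wk, LD at 8 wk, SD at 3 wk and SD at 8 wk, and at most 207 on any array of the other slides. NM_013547 stood at −4.83 in LD 3-wk replicate 4, NM_153539 at −2.76 in SD 8-wk replicate 4 and NM_008381 at 6.97 in SD 3-wk replicate 1. The test of a difference in age change between photoperiods called 12 transcripts, among them NM_001033364 (6.17 on the log2 scale), NM_013547 (4.95) and ENSMUST00000088612 (−1.44).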

How the results depend on the processing

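Fits without slide 1, on pairs of slides, with outlier spots kept, with normexp or combining the block with quantile normalization were chosen after the data were seen. Planned but not run were normexp on mean signals and the tests of gene lists, for want of mean signals and gene symbols. The counts for SD against LD at 8 wk, the age change in LD, the age change in SD and the interaction were 193, 601, 1844 and 12, and in the same order: 528, 2394, 4655 and 35 with slide as a block; 335, 1499, 3503 and 32 with array weights. The same counts were 310, 2168, 4448 and 7 with the slide block without slide 1, and 543, 2476, 4747 and 26 with the slide block and quantile normalization. On slides 3 and 4 alone, with the block, they were 24, 1321, 1075 and 4. On slides 1 and 2 alone, with the block, the LD age change gave 0 (2563 at an unadjusted limma p under 0.05) and the interaction 20. Without slide 1 the age changes gave 1246 in LD and 2865 in SD, and the interaction 4. Fitting only the 2 groups compared gave 82 for SD against LD at 8 wk, 220 for the LD age change and 1729 for the SD age change. Fewer arrays enter the estimate of the spread in each of these fits, and why only some counts fell by much was not tested. With outlier spots kept the LD age change gave 935. A 2-fold minimum gave 348 for the LD and 955 for the SD age change. At 3 wk the count was 0, and 2 with array weights and 2 on slides 3 and 4 alone.

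Leaving out single arrays gave 0 to 1 at 3 wk, 118 to 241 at 8 wk, 232 to 682 for the LD age change, 1141 to 2201 for the SD age change and 6 to 49 for the interaction. The correlation of age changes was 0.573 to 0.719 and that of photoperiod differences 0.064 to 0.321. Without a filter on dim probes the correlations were 0.438 and 0.012, a setting that adds probes near background. On slides 1 and 2 alone they were 0.452 and −0.045, the latter of opposite sign. Where no construction is named, the cause was not tested. Quantile normalization, the median of detected probes, the deposited value table, no filter, only probes detected on all 16 arrays, the mean of probes, every probe on its own and no trend left each count within 1.5 times its main value. So did normexp, with 137, 470, 1456 and 9, of which 128, 418, 1348 and 5 were also called without it. A first run of normexp with local backgrounds as given made 2, 0, 16 and 0 calls. Local backgrounds over 2 times the array's median were then set to that median, which gave the normexp counts above. Scaling alternatives moved the median change by at most 0.038 (log2). Of 504 recomputed values for named transcripts, 0 changed sign and 59 lost the threshold. Many of them repeat the main estimate by construction, such as those from fits without an array of a group not compared. The transcripts were also picked for size, so 0 changes of sign adds no support. Low signal over background limits NM_153539 and NM_183191, which lost their calls with normexp (−1.87 and −1.15 on the log2 scale), and the sizes for other dim transcripts, among them NM_145594 (3.50 in LD, 2.06 with normexp). The offset in normexp shrinks log2 differences of dim probes by construction.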

Other observations

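The test in this part was chosen after the results had been seen. A hypothesis from the counts is that SD ovaries at 8 wk may lie farther along the age change seen in LD. For each slide, an axis was built from the LD age change on the other 3 slides, over the transcripts with an unadjusted p under 0.01 there (1561 to 2533), and the held-out arrays were placed on it, with that slide's LD 3-wk array at 0. At 8 wk the score was 0.726 ± 0.172 in LD and 0.908 ± 0.275 in SD (SD, n = 4). SD minus LD at 8 wk was 0.182 ± 0.187, above 0 on 3 of 4 slides, with an exact two-sided sign permutation p of 0.25, where the smallest p that 4 slides allow is 0.125. At 3 wk SD ovaries scored −0.061 ± 0.262 (exact permutation p = 0.625). The difference at 8 wk was 0.184 with quantile normalization, 0.193 with normexp and 0.194 over all 18648 transcripts measured on every array. The exact test cannot reach a p under 0.05 with 4 slides, so the hypothesis remains open.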
